A study of Mus musculus with 18 samples.

How the data were processed

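Expression was measured in 18 samples of fetal liver LSK cells on Illumina mouse bead arrays. Per the labels' protocols, RNA was purified on small-scale columns, checked by capillary electrophoresis, amplified and labelled with biotin. The non-normalized file holds 1 bead-summary intensity per probe and array, deposited on a linear scale, per the file headers; its values are positive and no background subtraction shows in them. Beside each intensity stands a column which, per the file headers, is a detection p-value, but its values behave as the reverse, a fraction that reaches 1 for bright probes. These deposited columns were therefore read as a score of 1 minus the detection p-value, and the rank correlation of score and intensity was at least 0.982 on every array. The processed values of the authors are on a log2 scale, judged from the values, since the labels do not name the software. All their columns had a median of 7.20 and correlated with the log2 of the raw intensity at 0.996 or more, which is how quantile normalization without background subtraction looks. All deposited columns of per-sample values were matched to samples, and 0 were left over.

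The raw intensities were background-corrected with the detection p-values, quantile-normalized and taken to log2 with limma's neqc (limma 3.58.1 in R 4.3.3, package data.table, version 1.17.8; offset 16). Probes detected at p below 0.05 on at least 3 arrays were kept, 19909 of 45281. The raw median intensity was 124.4 to 202.8 per array. No pair of arrays was identical, and the highest correlation between arrays was 0.990. The first principal component held 26.8% of the variance and the second 14.0%. Symbols were brought up to date with a table of RefSeq genes used for names only: 29702 probes had a current symbol, 5288 were updated through their RefSeq accession and 1677 through a synonym, 4087 kept the symbol of the file and 4527 had none. Of the tested probes 1758 are graded Bad or No match in the probe annotation. Probe locations are given as in the file.

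A linear model with 1 mean per group was fitted to all 18 arrays, with moderated variances that follow the mean intensity (limma eBayes with trend; 14 residual and 6.99 prior degrees of freedom). Each mutant was compared with all 7 wild types and with each other mutant, which makes 6 comparisons. P-values were adjusted by Benjamini and Hochberg over the 19909 probes of each comparison, and a gene was called at an adjusted p below 0.05 through its brightest kept probe, which gave 11936 genes. SE is the moderated standard error of the log2 change. Where a gene was detected on no array of the lower group, the change is given as a bound: the mean of the higher group over the mean, in the lower group, of whichever is higher on each array, the lowest detected signal or the probe itself.

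Gene lists for Polycomb and related factors, blood lineages, other cell types of the fetal liver and cell states were fixed before the data were examined, 32 in all. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. For called lists, the members that pass when adjusted over the list alone are counted beside those that pass over all genes. Genes named in the text follow a rule. For each mutant against wild type these are the 10 largest rises and 10 largest falls among called genes with a symbol whose mutant arrays all lie on the same side of the wild-type mean. Added to these are up to 4 called members of each list and the targeted gene. Between mutants they are the 5 largest each way. Where under 5 genes were called, the 3 smallest p-values each way are named as not passing. List members that pass only within their list serve as examples.

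The fit was tested on simulated data with 50 changed genes per size among 11936. A log2 change of 1 was recovered for 78%, 84% and 84% of genes with the group sizes of Bmi1-/-, Suz12Plt8/+ and Yy1+/- against wild type, and a change of 0.5 for 24%, 28% and 20%. False calls were 6 of 154, 3 of 156 and 5 of 154. The simulated noise was independent between probes, so these rates leave out any structure that genes share across the arrays. The correlation of effects between mutants was set against 100 simulations in which the mutant groups do not differ from wild type.

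Alternatives planned before the files were opened were other normalizations (quantile without background correction, median scaling, the authors' values), other filters and probe summaries, only the groups compared and wild types of the same line alone. Array weights, no variance trend, the replicate number as a block, other list tests and leaving out each array in turn were planned as well. A block for slides was not run because the files name no slides. Alternatives chosen after seeing the data were leaving out wild-type arrays 2 and 3, the mean of the hepatocyte list as a covariate, and leaving out probes graded Bad or No match.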

Results

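RNA of fetal liver LSK cells was measured on 18 Illumina mouse bead arrays. LSK cells are the lineage-negative, Sca-1-positive and c-Kit-positive fraction, which holds haematopoietic stem cells and early progenitors. The samples were 3 Bmi1-/-, 4 Suz12Plt8/+, 4 Yy1+/- and 7 wild type, and the wild types came from the Bmi1 line (2), the Suz12 line (2) and the Yy1 line (3). Bmi1 is a subunit of Polycomb repressive complex PRC1, Suz12 is a core subunit of the histone methyltransferase complex PRC2, and Yy1 is a zinc-finger transcription factor related to a DNA-binding Polycomb protein of the fly. The series was made to compare what loss of each of these factors does to stem and progenitor cells. Between 16221 and 18077 of the 45281 probes were detected per array, 35.8% to 39.9%, and 11936 genes were tested, each through 1 probe. The number of arrays limits the precision. The labels do not say that the samples came from separate embryos, so the p-values measure only the spread between these samples, which may be technical.

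The targeted genes did not check the labels. The Bmi1 probe (chromosome 2, 18606017 to 18606066; the build of all probe locations is not given in the sources used here) read 7.54 ± 0.18 log2 units (SD, n = 3; 7.40 to 7.74) in Bmi1-/- and 7.95 ± 0.75 (SD, n = 7; 6.90 to 8.82) in wild type. That difference of -0.41 (SE 0.33) did not pass (adjusted p = 0.887) and was 0.52 in the other direction against the Bmi1+/+ arrays alone, which read 7.01 ± 0.17 (SD, n = 2). The labels do not say whether the probe lies in the deleted part of Bmi1. The detected Suz12 probe (chromosome 11, 79847118 to 79847167) read 12.72 ± 0.20 in Suz12Plt8/+ (SD, n = 4) and 12.81 ± 0.13 in wild type (SD, n = 7), with a log2 difference of -0.09 (SE 0.10, adjusted p = 0.845). A mutant allele need not change the amount of Suz12 RNA. The Yy1 probe (chromosome 12, 110054111 to 110054160) was not detected on any array, with means of 4.71 in Yy1+/- and 4.81 in wild type. The gene lists of Polycomb subunits were not called in any mutant. Camera's adjusted p for PRC1 subunits was 0.816 in Bmi1-/-, 0.431 in Suz12Plt8/+ and 0.536 in Yy1+/-, and for PRC2 subunits 0.0993, 0.702 and 0.180. Adjusted over the PRC1 list alone, the subunit genes Phc2 in Bmi1-/- (-0.40, SE 0.10, adjusted p = 0.01765) and Cbx2 in Suz12Plt8/+ (-0.55, SE 0.15, adjusted p = 0.0320) were lower, and neither passed over all genes. The list of Yy1 and its partners had a list p of 0.631, 0.201 and 0.920. These lists and those of cyclin-dependent kinase inhibitors, multipotent and early lymphoid progenitors, p53 targets, the unfolded protein response, oxidative stress, glycolysis and sex-linked genes were called in none of the 6 comparisons, the lowest adjusted p being 0.0642 for oxidative stress in Yy1+/-.

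Bmi1-/- samples had higher levels of a Hox gene and of several eosinophil granule genes than wild type. Hoxc6 (chromosome 15, 102842230 to 102842279), a homeobox gene of the Hoxc cluster, was higher in Bmi1-/- than in wild type (log2 change 2.84, SE 0.21, adjusted p = 1.47e-07). It read 8.41 ± 0.49 (SD, n = 3) against 5.57 ± 0.23 (SD, n = 7), and only 2 of the 7 wild-type arrays detected it, which leaves the size of the change imprecise. The eosinophil-associated ribonucleases Ear4, Ear10, Ear6 and Ear2 rose by 1.78, 1.77, 1.74 and 1.73 on the log2 scale (SE 0.31, 0.27, 0.26 and 0.26), 3.43-fold for Ear4 and 3.32-fold for Ear2. Prg2 (chromosome 2, 84823648 to 84823697), the eosinophil major basic protein, rose by 1.51 (SE 0.26, adjusted p = 0.0224), and Epx (chromosome 11, 87677696 to 87677745), the eosinophil peroxidase, was at least 1.34-fold higher (adjusted p = 0.0321). In Yy1+/- Prg2 was higher than in wild type too, by 0.81 (SE 0.24), without passing over all genes (adjusted p = 0.248). Between Bmi1-/- and Yy1+/- neither Prg2 (0.71, SE 0.29, adjusted p = 0.578) nor Epx (0.455) passed over all genes, and both did when adjusted over the mast cell and basophil list alone. Foxa1 (chromosome 12, 58642124 to 58642173), a pioneer transcription factor of endoderm, was at least 1.73-fold higher (adjusted p = 0.000488). Nrn1 (chromosome 13, 36817911 to 36817960), a neuronal surface protein, was at least 2.78-fold higher (adjusted p = 0.0238), and Lrig1 (chromosome 6, 94554937 to 94554986), an inhibitor of growth factor receptors, at least 1.40-fold higher (adjusted p = 0.00403). These bounds apply because no wild-type array detected the gene. The Ear genes are close paralogs, so their probes may read one another, and the other probes of Ear2 changed by 1.98 and 1.65.

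In all, 10 genes rose and 0 fell in Bmi1-/- against wild type in limma at the adjusted threshold, and 706 had an unadjusted p below 0.05, where 596.8 were expected with no effect. The count was 3 without Bmi1-/- replicate 1, 2 without Bmi1-/- replicate 3 and 6 without wild-type replicate 5 or without replicate 7, and it was 4 in a fit of those groups alone, 3 against the Bmi1+/+ arrays alone and 21 without wild-type replicates 2 and 3. Hoxc6 passed in all 24 alternatives, and Foxa1 in the 23 that tested it. Foxa1 was detected on the 3 Bmi1-/- arrays alone, the fewest that the detection filter allows. Runs that left out 1 array did not repeat this filter. Epx failed to pass in 14 of 23 (adjusted p up to 0.380), Nrn1 in 10 of 24 (up to 0.9997), Ear4 and Prg2 in 8 of 24 each (up to 0.520), Ear10 in 5 of 24, Ear2 and Ear6 in 4 of 24 each, and Lrig1 in 4 of 23.

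**Figure D1:**
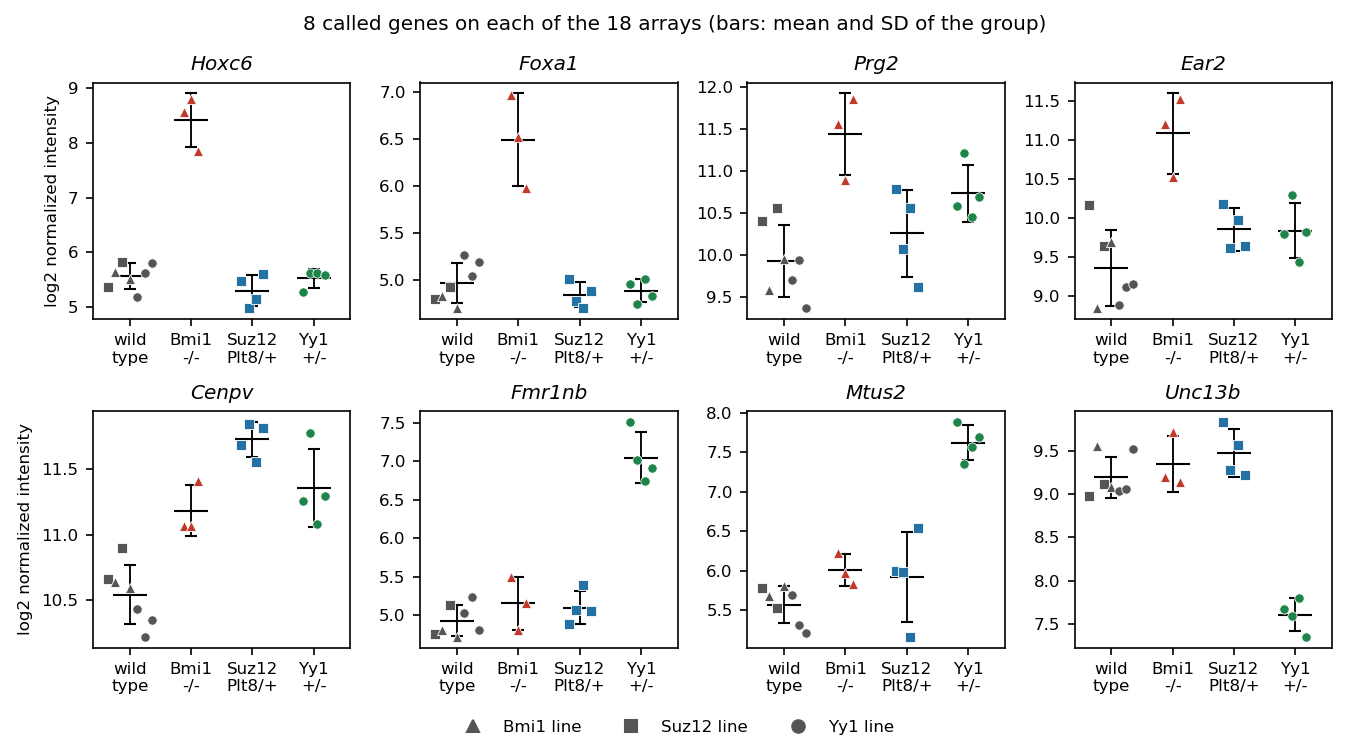
Log2 normalized intensity of 8 called genes on each of the 18 arrays, by genotype (x axis), with the mouse line as the marker shape and bars for the mean and SD of each group. Hoxc6 and Foxa1 stood apart in Bmi1-/-, Fmr1nb and Mtus2 were high and Unc13b was low in Yy1+/-, and Cenpv was above wild type in Suz12Plt8/+ (11.73 against 10.54).

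Of the 32 gene lists, 11 were called in Bmi1-/-, all higher, and 3 of these calls held with an estimated correlation between genes. The list of developmental regulators commonly bound by Polycomb was higher by a mean of 0.51 (camera adjusted p = 9.53e-05, adjusted p = 0.0133 with an estimated correlation). With no detection filter this list was not called (adjusted p = 0.653). Foxa1 passed the filter only through Bmi1-/- arrays, the group in which it was high, so the filter itself favours this call. Most genes of the list were not measured. Of its 8 measured genes 1 rose (Foxa1), and 3 did when adjusted over the list alone, with Isl1, a LIM-homeobox factor, at 1.09 (SE 0.22) and Pitx2 at 0.90 (SE 0.35). The mast cell and basophil list was higher by 0.60 (adjusted p = 7.75e-05, and 0.0392 with an estimated correlation), and the 2 of its 6 genes that rose were Prg2 and Epx, whose products are best known from eosinophil granules. Epx, too, passed the filter only through Bmi1-/- arrays. Adjusted over the list alone, 3 rose and Fcer1a, a chain of the IgE receptor, was lower by at least 1.05-fold. The T and NK cell list was higher by 0.41 (adjusted p = 0.00313, and 0.0392 with an estimated correlation). None of its 6 genes passed over all genes, and Cd3g and Thy1 (0.77, SE 0.29) did when adjusted over the list alone.

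Genes of the neutrophil and monocyte lineage were higher by a mean of 0.44 in Bmi1-/- (adjusted p = 1.90e-06, adjusted p = 0.138 with an estimated correlation), with 0 of 24 passing over all genes and 7 when adjusted over the list alone. Among these were Camp (1.56, SE 0.40), S100a8 (0.98, SE 0.25) and Elane (0.87, SE 0.25), which encode granule and cytosolic proteins of myeloid cells. The other Hox clusters were higher by 0.53 (adjusted p = 0.00337, and 0.138 with an estimated correlation) and this rests on Hoxc6, since the other 6 measured genes lay between -0.08 and 0.34 and none passed. Against the Bmi1+/+ arrays alone the list was not called (adjusted p = 0.192). The immediate early list was higher by 0.30 (0.00648, and adjusted p = 0.378 with an estimated correlation), with Fosb at 1.78 (SE 0.49) and Fos at 0.98 (SE 0.31) among the 4 of 22 that passed when adjusted over the list alone. The fetal-type stem cell list (adjusted p = 0.000930), the mesenchymal list (0.0109), the oxidative phosphorylation list (0.000181) and the megakaryocyte and platelet list (0.0366) were also called, and their adjusted p with an estimated correlation was 0.147, 0.0741, 0.138 and 0.433. None of their genes passed over all genes, and 1 (Grb10, an imprinted gene, 0.72, SE 0.20), 2, 0 and 1 did when adjusted over the list alone. The list of hepatocyte genes, markers of the cells among which fetal liver blood cells lie, was higher in the same arrays by 0.63 (adjusted p = 0.000321, adjusted p = 0.433 with an estimated correlation), and an exact permutation test of its mean per array gave p = 0.117. The gene of the cell-cycle inhibitor p16, Cdkn2a, a known target of Bmi1, did not differ (0.01, SE 0.21, adjusted p = 0.994), at low means of 6.01 in Bmi1-/- and 6.00 in wild type. Of the same list of cyclin-dependent kinase inhibitors, which was not called, Cdkn2c was higher by 0.95 (SE 0.24). Cdkn2c passed when adjusted over the list alone (adjusted p = 0.00538) and not over all genes (0.349).

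A single gene was called in Suz12Plt8/+ against wild type. Cenpv (chromosome 11, 62338712 to 62338761), which encodes a centromere protein, rose by 1.19 (SE 0.13, 2.28-fold, adjusted p = 0.000310), from 10.54 ± 0.23 (SD, n = 7) to 11.73 ± 0.13 (SD, n = 4). Cenpv lies within 20 Mb of the Suz12 probe. Of the 430 genes in that window 7.44% had an unadjusted p below 0.05, against 7.91% of the others (Fisher's exact p = 0.785). An effect of DNA linked to the mutant allele on Cenpv was not told apart from an effect of Suz12. The genes next in rank did not pass. On the side of higher values these were Slpi, a protease inhibitor (1.26, SE 0.21, adjusted p = 0.0697), Zbtb8a (1.03, SE 0.19, 0.125) and Pf4, a platelet chemokine (1.75, SE 0.33, 0.149). On the side of lower values they were the antiviral gene Oas2 (-0.87, SE 0.19, adjusted p = 0.243, through a probe graded Bad), the inflammasome gene Nlrc4 (-0.74, SE 0.17, 0.295) and Il6ra, a chain of the interleukin receptor (-0.89, SE 0.21, 0.301). An unadjusted p below 0.05 was seen for 942 genes, against 596.8 expected. Against the Suz12+/+ arrays alone no gene was called and Cenpv was at 0.94 (adjusted p = 0.262). Without wild-type replicate 2, wild-type replicate 3 or Suz12Plt8/+ replicate 3 the count was 2, and it reached 9 with the mean of all probes of a gene.

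In Suz12Plt8/+, 9 lists were called, of which none held with an estimated correlation and 0 were called by fry. Hepatocyte genes were higher by a mean of 1.00 (camera adjusted p = 2.99e-12, adjusted p = 0.243 with an estimated correlation), all 19 above wild type. When adjusted over the list alone 11 passed, and 0 over all genes. Among them were Apoa2 (1.77, SE 0.49) and Ttr (1.57, SE 0.50), which encode plasma proteins made by the liver. The mean of the list per array was 8.99 in Suz12Plt8/+ and 7.99 ± 0.53 in wild type (SD, n = 7), with an exact permutation p of 0.0364 (0.0545 after adjustment over the 3 mutants). Erythroid genes were higher on the same arrays, 27 of 28 of them, by 0.47 (adjusted p = 1.18e-06, and 0.325 with an estimated correlation), with embryonic globin Hbb-y at 2.62 (SE 0.87) and 0 genes passing. Megakaryocyte and platelet genes were higher by 0.36 (adjusted p = 1.01e-06, adjusted p = 0.243 with an estimated correlation), with 0 passing over all genes. When adjusted over the list alone 7 of 25 passed, among them Pf4, Gp1bb (1.29, SE 0.28) and Gp5 (1.14, SE 0.27), parts of platelet granules and of the receptor for von Willebrand factor.

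B cell genes were higher in Suz12Plt8/+ by 0.51 (adjusted p = 0.000774, and 0.297 with an estimated correlation), with 3 of 11 passing when adjusted over the list alone, Vpreb1 (1.60, SE 0.39), Pou2af1 (1.18, SE 0.43) and Cd19 (0.55, SE 0.20). Of the 7 wild-type arrays 2 detected Pou2af1 and 1 detected Cd19, so the sizes of these 2 changes are imprecise. Neutrophil and monocyte genes were higher by 0.28 (adjusted p = 0.000384, and 0.297 with an estimated correlation), with 7 of 24 passing when adjusted over the list alone, among them Ly6c1 (1.32, SE 0.32), Ms4a3 (1.20, SE 0.28) and Elane (0.99, SE 0.23). The dendritic cell list (adjusted p = 0.0124) and the ribosomal protein list (0.000159) were higher as well, each at an adjusted p of 0.243 with an estimated correlation, with 1 and 0 genes passing when adjusted over the list alone and 0 over all genes. Immediate early genes were lower by a mean of -0.38 (adjusted p = 1.10e-06, adjusted p = 0.243 with an estimated correlation). Jun at -0.73 (SE 0.18), Junb at -0.55 (SE 0.19) and Klf2 at -1.09 (SE 0.38) were among the 6 of 22 that passed when adjusted over the list alone. Interferon-stimulated genes were lower by -0.23 (adjusted p = 5.69e-05, and 0.243 with an estimated correlation), with 24 of 28 below wild type and 3 passing when adjusted over the list alone, Oas2, Irf7 (-0.90, SE 0.26) and Dhx58 (-0.47, SE 0.14). Of 100 splits of these arrays into groups of 4 and 7, 5 called as many lists.

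**Figure D2:**
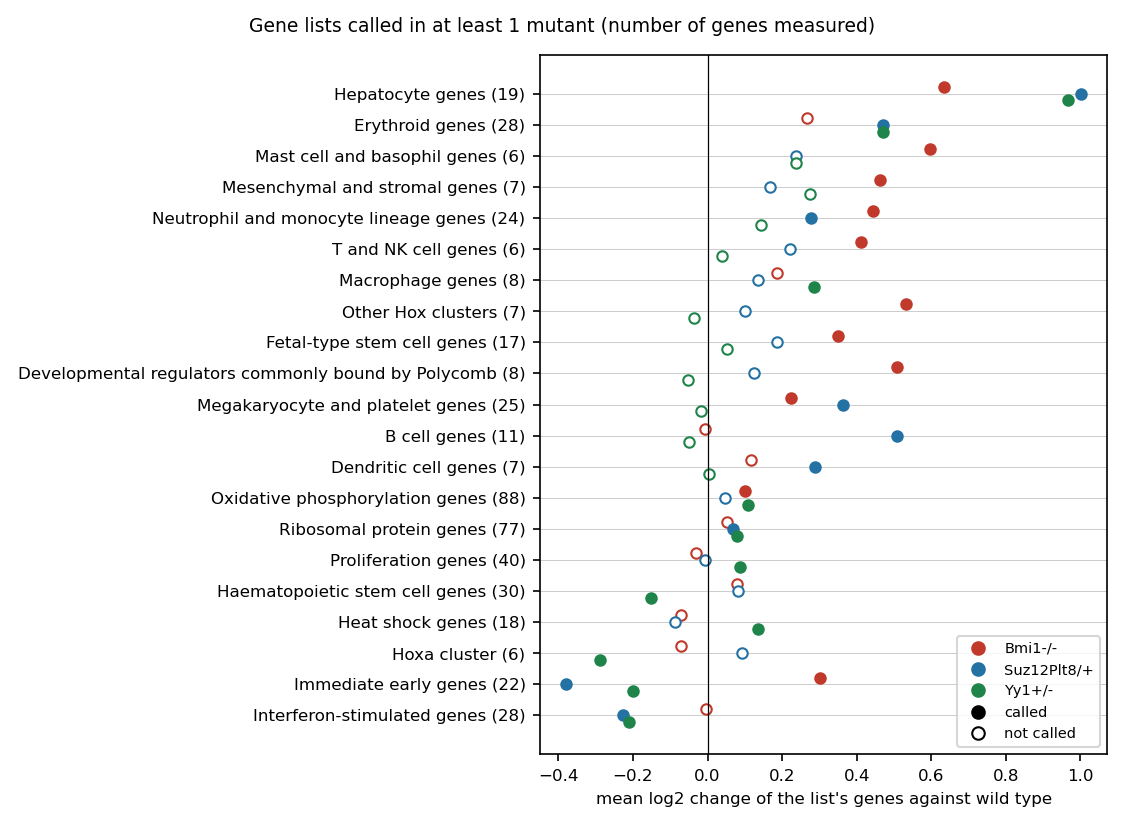
Mean log2 change against wild type (x axis) of each gene list called by camera in at least 1 mutant, with the number of measured genes in brackets; colours stand for the mutants and filled points for calls. The hepatocyte list had the highest mean in Suz12Plt8/+ and Yy1+/- (1.00 and 0.97), and the immediate early list lay at 0.30 in Bmi1-/- and -0.38 in Suz12Plt8/+.

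Yy1+/- cells differed from wild type in 33 genes, of which 7 rose and 26 fell. Fmr1nb, a cancer-testis gene whose probe has no location in the file, was at least 2.54-fold higher (adjusted p = 1.38e-06; 7.05 ± 0.33 (SD, n = 4) in Yy1+/-, not detected in wild type). Mtus2 (chromosome 5, 149118230 to 149118279), which encodes a microtubule-associated protein, rose by 2.05 (SE 0.21, adjusted p = 1.45e-05; 2 of 7 wild-type arrays detected it), and Hormad2 (chromosome 11, 4245936 to 4245985), a protein of meiotic chromosome axes, rose by 1.33 (SE 0.18, adjusted p = 0.000794). Gpat2 (chromosome 2, 127261751 to 127261800), an acyltransferase expressed mainly in testis, was at least 1.22-fold higher (adjusted p = 9.00e-05), and Cenpv rose by 0.81 (SE 0.13, adjusted p = 0.00544). BC050987 rose by 0.99 (SE 0.20), and AK006252 by 0.89 (SE 0.14) through a probe graded Bad.

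The largest fall in Yy1+/- was in Unc13b (chromosome 4, 43277534 to 43277583), which encodes a protein that primes vesicles for release, by -1.59 (SE 0.16, 3.02-fold lower, adjusted p = 1.45e-05), from 9.20 ± 0.24 (SD, n = 7) to 7.60 ± 0.19 (SD, n = 4). BC058760 fell by 1.33 (SE 0.16, adjusted p = 0.000151). Wfdc18 and Wfdc17, neighbouring genes of secreted WAP-domain proteins (chromosome 11, 83524662 to 83524711 and 83517604 to 83517653), fell by 1.30 (SE 0.17) and 1.11 (SE 0.16). The zinc-finger gene Zfp37 was at least 1.22-fold and the centrosomal gene Cep126 at least 1.53-fold lower. Mrgpra2b, a receptor gene, changed by -1.06 (SE 0.20), and 4933402N22Rik and Speer1 by -1.03 each (SE 0.22 and 0.17). Col17a1, a collagen of epithelial attachment plaques, was lower too (adjusted p = 0.0126), but no Yy1+/- array detected its probe, so no size is given. An unadjusted p below 0.05 was seen for 1152 genes, against 596.8 expected. The count was 16 without Yy1+/- replicate 1, 17 without Yy1+/- replicate 4, 50 with the mean of all probes of a gene, 20 in a fit of those groups alone, 73 with array weights and 60 without wild-type replicates 2 and 3 for Yy1+/- against wild type. Quantile normalization without background correction gave 10 rises and 18 falls. Fmr1nb, Mtus2, Hormad2, Unc13b, BC058760, Wfdc18 and Wfdc17 passed in all 25 alternatives, and Gpat2 in the 24 that tested it. Among the others, 4933402N22Rik failed to pass in 16 of 25 (adjusted p up to 0.240), BC050987 in 15 (up to 0.185), Mrgpra2b in 7, Col17a1 and Zfp37 in 5 each, Speer1 in 2, AK006252 in 2 of 24, and Cenpv and Cep126 in 1 each.

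In Yy1+/-, 11 lists were called, none of which held with an estimated correlation, and fry called 0. Genes of haematopoietic stem cells were lower by a mean of -0.15 (camera adjusted p = 0.000965, adjusted p = 0.291 with an estimated correlation), 22 of 30 below wild type. Over all genes 0 passed, and 3 did when adjusted over the list alone, Txnip (-0.34, SE 0.09), Ctnnal1 (-0.48, SE 0.14) and Mpl (-0.34, SE 0.10), the last the thrombopoietin receptor. The Hoxa cluster was lower by -0.29 (adjusted p = 0.00876, and 0.221 with an estimated correlation), and of its 6 genes Hoxa5 (-0.49, SE 0.15) passed when adjusted over the list alone and Hoxa9 (-0.51, SE 0.22) did not. Interferon-stimulated genes were lower by -0.21 (adjusted p = 8.55e-05, and 0.223 with an estimated correlation), 23 of 28 of them, with Rsad2 at -0.61 (SE 0.18) and Gbp2 at -0.55 (SE 0.17) and 0 passing over the list alone. Immediate early genes were lower by -0.20 (adjusted p = 0.00513, and 0.322 with an estimated correlation), with Ier3 at -0.45 (SE 0.13) as the only gene of 22 that passed when adjusted over the list alone.

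Hepatocyte genes were higher in Yy1+/- by a mean of 0.97 (camera adjusted p = 3.59e-08, adjusted p = 0.291 with an estimated correlation). Adjusted over the list alone, 14 of 19 rose, among them Afp (1.39, SE 0.45) and Apoa2 (1.57, SE 0.49), and 1 fell, Dlk1 (-0.62, SE 0.15), an imprinted gene that stem cells also express; 0 passed over all genes. The exact permutation p of the mean per array was 0.0333 (0.0545 over the 3 mutants). On the same arrays erythroid genes were higher by 0.47 (adjusted p = 8.55e-05, and 0.422 with an estimated correlation) and macrophage genes by 0.29 (0.0387, and adjusted p = 0.221 with an estimated correlation), with 0 genes of either list passing. The proliferation list was higher by 0.09 (adjusted p = 0.0149), with Ccne1, cyclin E, at 0.57 (SE 0.15) as the 1 gene of 40 that passed when adjusted over the list alone. The heat shock list (adjusted p = 0.0387), the ribosomal protein list (0.000191) and the oxidative phosphorylation list (8.55e-05) were higher by 0.14, 0.08 and 0.11, with 0 genes passing. None of these 4 calls held with an estimated correlation (adjusted p = 0.221, 0.221, 0.223 and 0.221). Of 100 splits of these arrays into groups of 4 and 7, 7 called as many lists.

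**Figure D3:**
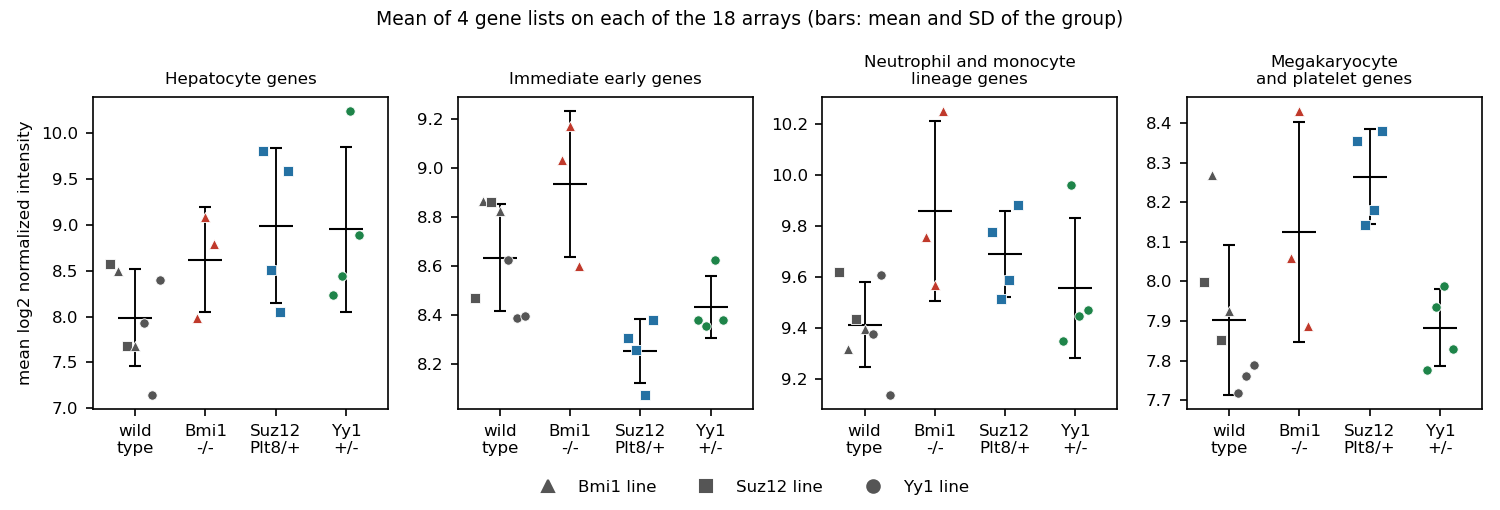
Mean log2 normalized intensity of 4 gene lists on each of the 18 arrays, by genotype (x axis), with the mouse line as the marker shape and bars for the mean and SD of each group. The hepatocyte list averaged 7.99 in wild type, 8.62 in Bmi1-/-, 8.99 in Suz12Plt8/+ and 8.95 in Yy1+/-, with wide spread inside each group.

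Compared directly, Bmi1-/- and Suz12Plt8/+ differed in 3 genes, all higher in Bmi1-/-. Hoxc6 was at least 6.20-fold (adjusted p = 1.86e-07), Foxa1 at least 1.64-fold (0.000736) and Epx at least 1.27-fold higher (adjusted p = 0.0201). Hoxc6 passed in all 21 alternatives, whereas Epx failed to pass in 7 of 20 (adjusted p up to 0.814) and Foxa1 in 1 of 20 (0.372). Not passing were Jun at 1.22 (SE 0.22, adjusted p = 0.0749), Insm1 (at least 1.72-fold higher, probe graded Bad, 0.0964) and Lrig1 (at least 1.33-fold higher, 0.0979). On the lower side these were Pira11 (at least 1.55-fold lower, 0.121), AK082757 at -0.66 (SE 0.15, 0.177) and Arl5a at -1.95 (SE 0.46, 0.211). Immediate early genes differed between the mutants by a mean of 0.68 (camera adjusted p = 1.37e-09, adjusted p = 0.186 with an estimated correlation), 19 of 22 higher in Bmi1-/-. Fosb at 2.71 (SE 0.54), Klf2 at 2.01 (SE 0.46) and Fos at 1.64 (SE 0.34) were among the 9 that passed when adjusted over the list alone. The list of Polycomb-bound regulators was higher by 0.38 (adjusted p = 0.0348, and 0.195 with an estimated correlation), with Foxa1 as the 1 of its 8 genes that passed. Foxa1 entered the list only through Bmi1-/- arrays. Interferon-stimulated genes were higher by 0.22 (adjusted p = 0.00584, and 0.454 with an estimated correlation). B cell genes were lower in Bmi1-/- by -0.52 (adjusted p = 0.00448, and 0.454 with an estimated correlation), as were the hepatocyte list (-0.37; 0.0243, and 0.613 with an estimated correlation) and the megakaryocyte and platelet list (-0.14; 0.0460, and 0.491). Adjusted over the list alone, 2 B cell genes passed and 0 of the interferon, hepatocyte and megakaryocyte lists. In limma 1009 genes had an unadjusted p below 0.05, and the gene count was 6 without Bmi1-/- replicate 3, 156 in a fit of those groups alone, 15 with median scaling, 32 with array weights and 1 against line-matched wild types. Called lists numbered 2 without Suz12Plt8/+ replicate 1 or replicate 4 and 3 without Bmi1-/- replicate 1, and 13 of 35 splits of these 7 arrays called as many as the 6.

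Between Bmi1-/- and Yy1+/-, 36 genes differed, 32 higher and 4 lower in Bmi1-/-. Hoxc6 (at least 6.00-fold, adjusted p = 7.69e-07) and Foxa1 (at least 1.59-fold, 0.000453) were again higher, as was Isl1 (chromosome 13, 117088838 to 117088887) by 1.53 (SE 0.25, adjusted p = 0.00480). Only 1 of 4 Yy1+/- arrays detected Isl1, which leaves the size of its change imprecise. Stfa2 (chromosome 16, 36404076 to 36404125), a protease inhibitor of the stefin family, was higher by 2.73 (SE 0.56, adjusted p = 0.0446), Mb21d2 by 1.83 (SE 0.34), Unc13b by 1.75 (SE 0.20), and the platelet chemokine gene Ppbp (chromosome 5, 91198622 to 91198671) at least 1.94-fold. Lower in Bmi1-/- were Fmr1nb (at least 2.53-fold lower), Hormad2 (-1.68, SE 0.22), Mtus2 (-1.61, SE 0.26) and Gpat2 (at least 1.22-fold lower). Hoxc6 passed in all 21 alternatives, and Foxa1 in the 20 that tested it. Ppbp failed to pass in 16 of 21 (adjusted p up to 0.723), Stfa2 in 11 (up to 0.686), Mb21d2 in 7 (up to 0.772), Isl1 in 2, Gpat2 in 2 of 20, and Unc13b, Fmr1nb, Hormad2 and Mtus2 in 1 each. Of the 13 called lists 3 held with an estimated correlation, each at an adjusted p of 0.0364. The Polycomb-bound regulators were higher in Bmi1-/- by 0.56 (camera adjusted p = 0.00274), with 2 of 8 genes passing and 3 when adjusted over the list alone. Foxa1 is among these and passed the detection filter only through Bmi1-/- arrays. The call of this list ended with no detection filter (0.948) and against line-matched wild types (0.184). Proliferation genes (-0.12, 0.00140, 33 of 40 lower) and heat shock genes (-0.21, 0.00424, 14 of 18 lower) were lower with 0 genes passing.

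The other called lists were higher in Bmi1-/- than in Yy1+/-. Haematopoietic stem cell genes were higher by 0.23 (adjusted p = 0.000108, adjusted p = 0.190 with an estimated correlation), with 2 of 30 passing when adjusted over the list alone, Ctnnal1 (0.71, SE 0.17) and Ly6a, which encodes Sca-1 (0.66, SE 0.17). Immediate early genes were higher by 0.50 (3.94e-06, and adjusted p = 0.133 with an estimated correlation), fetal-type stem cell genes by 0.30 (0.000746, and 0.1504), neutrophil and monocyte genes by 0.30 (0.00195, and 0.340), interferon-stimulated genes by 0.21 (0.00303, and 0.340) and endothelial genes by 0.24 (0.00471, and 0.340). The other Hox clusters (0.57; 0.00753, and 0.181), T and NK cell genes (0.37; 0.0184, and 0.114), megakaryocyte and platelet genes (0.24; 0.0231, and 0.399) and mast cell and basophil genes (0.36; 0.0398, and 0.286) were higher too, the second value of each pair being the adjusted p with an estimated correlation. Passing when adjusted over the list alone were 6 immediate early, 4 fetal-type, 1 neutrophil and monocyte, 1 interferon-stimulated and 3 endothelial genes (Clec4g, Emcn and Robo4). In the last 4 lists these were 1, 0, 2 and 3, with Fcer1a lower, and over all genes only Hoxc6 and Ppbp passed. Hepatocyte genes differed by -0.33 (adjusted p = 0.0883) and were not called. In limma 1011 genes had an unadjusted p below 0.05, and the count of 36 was 16 without Yy1+/- replicate 1, 15 without Bmi1-/- replicate 1, 11 without Bmi1-/- replicate 2, 23 without Yy1+/- replicate 2, 23 without Yy1+/- replicate 3 and 15 without Yy1+/- replicate 4. For Bmi1-/- against Yy1+/- it was 2 against line-matched wild types, 20 in a fit of those groups alone, 139 with array weights and 94 without wild-type replicates 2 and 3, and line-matched wild types left 2 lists.

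Suz12Plt8/+ and Yy1+/- differed in 76 genes, with 65 higher and 11 lower in Suz12Plt8/+. Unc13b was higher by 1.88 (SE 0.18, adjusted p = 1.54e-05), Prune2 (chromosome 19, 17298160 to 17298209) by 1.79 (SE 0.24), Pf4 (chromosome 5, 91202280 to 91202329) by 1.69 (SE 0.37, adjusted p = 0.0401) and BC058760 by 1.40 (SE 0.18), and Macroh2a2 (chromosome 10, 61220555 to 61220604), which encodes a variant histone, at least 2.28-fold. Lyz1 (chromosome 10, 116724980 to 116725029), a lysozyme of myeloid cells, was higher by 0.65 (SE 0.11, adjusted p = 0.00823) and Dlk1 (chromosome 12, 110698675 to 110698724) by 0.79 (SE 0.17, adjusted p = 0.0288). Lower in Suz12Plt8/+ were Fmr1nb (at least 2.41-fold lower), Mtus2 (-1.70, SE 0.24), Hormad2 (-1.60, SE 0.21), BC050987 (-1.22, SE 0.23) and Evc2 (chromosome 5, 37815962 to 37816011), a gene of Hedgehog signalling at the cilium (-1.20, SE 0.25). Unc13b, Prune2, Fmr1nb and Hormad2 passed in every alternative, whereas Pf4 failed to pass in 11 of 22 (adjusted p up to 0.688), Dlk1, Evc2 and Macroh2a2 in 9 each, BC050987 in 4, Lyz1 in 3, and BC058760 and Mtus2 in 1 each. Of the 5 called lists none held with an estimated correlation. Megakaryocyte and platelet genes were higher by 0.38 (camera adjusted p = 3.13e-05, adjusted p = 0.265 with an estimated correlation), 20 of 25 of them, with 1 passing over all genes (Pf4) and 5 when adjusted over the list alone. Haematopoietic stem cell genes were higher by 0.23 (3.37e-05, and 0.306), with 7 of 30 passing when adjusted over the list alone, among them Mecom (0.68, SE 0.19), Mllt3 (0.83, SE 0.24) and Gfi1 (0.41, SE 0.13), all transcriptional regulators. The Hoxa cluster was higher by 0.38 (0.00414, and 0.248), with Hoxa5 (0.66, SE 0.16), Hoxa7 (0.56, SE 0.17) and Hoxa9 (0.71, SE 0.24) passing when adjusted over the list alone, and B cell genes by 0.56 (0.00589, and 0.468). Heat shock genes were lower by -0.22 (0.00414, and 0.0697). In each of these last 2 lists 1 gene passed when adjusted over the list alone. Hepatocyte genes differed by 0.04 (adjusted p = 0.670).

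The count of 76 depended on single arrays. It was 34 without Yy1+/- replicate 1, 42 without Yy1+/- replicate 2, 38 without Yy1+/- replicate 4, 34 without Suz12Plt8/+ replicate 1, 49 without Suz12Plt8/+ replicate 2 and 26 without Suz12Plt8/+ replicate 3. For Suz12Plt8/+ against Yy1+/- it was also 142 in a fit of those groups alone, 385 with array weights, 172 without wild-type replicates 2 and 3, 6 against line-matched wild types and 15 with median scaling, which split as 11 higher and 4 lower. In limma 1434 genes had an unadjusted p below 0.05, and called lists numbered 10 without Yy1+/- replicate 3 and 1 against line-matched wild types.

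The effects of the 3 mutants were set against one another over the 11936 genes, which are not independent replicates. All were measured against the same 7 wild-type arrays, which alone gives a correlation above 0. Pearson's r was 0.258 between Bmi1-/- and Suz12Plt8/+, 0.316 between Bmi1-/- and Yy1+/- and 0.284 between Suz12Plt8/+ and Yy1+/-. Simulated unchanged groups against the same arrays, with each gene drawn independently, gave 0.330, 0.331 and 0.364. Whole arrays of residuals were also drawn again, which keeps the correlation between genes. The 95% ranges of r were then -0.16 to 0.79, -0.37 to 0.78 and -0.28 to 0.74, and each observed r lay inside its range. The covariances were 0.0139, 0.0171 and 0.0155, against 0.0140 simulated for each pair. With the wild types split between the mutants, the median r over 70 splits was 0.0223, 0.0567 and 0.00419, and against line-matched wild types, which share no array, r was 0.281, 0.0255 and -0.106. The calls shared 1 gene, Cenpv, which rose in Suz12Plt8/+ and in Yy1+/-. Independent lists of those sizes would share 0.000587 genes, and simulated groups shared 0. The real lists are not independent, since both comparisons use the same 7 wild-type arrays. The simulated groups hold no changed genes, so hardly any can be called in them. Neither value therefore measures how far the overlap is from chance. Bmi1-/- shared 0 calls with either of the others.

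Wild-type lines (Suz12+/+, Bmi1+/+ and Yy1+/+ wild types) were compared to see whether they could be pooled. Limma's F test called 2 genes, the phosphatase gene Dusp23 (adjusted p = 0.0407) and the splicing factor gene Tra2b (0.0492), and 1437 genes had an unadjusted p below 0.05, against 596.8 expected. Tra2b read 9.90 in the Bmi1 line (n = 2), 11.53 in the Suz12 line (n = 2) and 11.72 in the Yy1 line (n = 3). The count was 683 without wild-type replicate 1, 139 without replicate 3, 25 without replicate 4 and 0 without replicate 2, 5 or 6. The 1437 genes exceed the 706, 942 and 1152 of Bmi1-/-, Suz12Plt8/+ and Yy1+/- against wild type. Comparisons with pooled wild types may therefore carry differences between lines. Against same-line wild types, 2.13%, 6.74% and 11.9% of genes outside 20 Mb of the targeted gene's probe had an unadjusted p below 0.05 in limma. Against all wild types these shares were 5.88%, 7.91% and 9.55%.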

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

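The tests of a genotype difference in hepatocyte genes, of cross-reading Ear probes, of the Bmi1 line and of the Yy1 line were chosen only after the result was seen. For the genes within 20 Mb of the Yy1 probe or of the Suz12 probe no prediction was written down at all. The predictions of the other tests below were written beforehand. An array was flagged when it lay far from the rest of its group. This was asked of 194 groups of values and met in 11, about as many as a rule that is met by chance in 1 of 20 groups would give.

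Hoxc6 was lowest on Yy1+/- replicate 1 at 5.276, the next array being at 5.595. Nlrc4 was lowest on wild-type replicate 7 at 6.061 (next 6.452). Prune2 was lowest on Suz12Plt8/+ replicate 4 at 7.828 (next 8.457). Evc2 was highest on Suz12Plt8/+ replicate 3 at 7.357 (next 7.091). Dlk1 was highest on Yy1+/- replicate 3 at 12.83 (next 12.09). Cep126 was lowest on wild-type replicate 1 at 5.993 (next 6.432). Of the list means, the Hoxa cluster was lowest on wild-type replicate 6 at 8.413 (next 8.638), haematopoietic stem cell genes lowest on Yy1+/- replicate 2 at 9.504 (next 9.684), B cell genes highest on Yy1+/- replicate 2 at 7.036 (next 6.238) and immediate early genes highest on Yy1+/- replicate 3 at 8.623 (next 8.378). Raw median intensity was highest on wild-type replicate 6 at 202.8 (next 155). Probes with no gene symbol that were called numbered 2 for Bmi1-/- against Yy1+/- and 2 for Suz12Plt8/+ against Yy1+/-, data no gene table reports on. Both lie on chromosome 7, at 16634334 to 16634383 (0.60, SE 0.12, and 0.64, SE 0.11) and at 126115831 to 126115880 (1.08, SE 0.22, and 0.98, SE 0.20), lower in Yy1+/- each time.

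Whether an arbitrary grouping of arrays could give the counts was tested by splitting the same arrays otherwise. For Bmi1-/- against wild type 4 of 100 splits called as many genes as the real 10, the highest other split calling 691. For Suz12Plt8/+ it was 4 of 100 (real 1, highest other 754) and for Yy1+/- 3 of 100 (real 33, highest other 684). Each share was thus below 5%, but none was adjusted over the comparisons, and for Suz12Plt8/+ the count is a single gene. Chance is therefore not firmly excluded. Splits that call this many genes point to a structure of the samples. The highest set apart wild-type replicates 1, 5 and 6 (691) and the same 3 with Yy1+/- replicate 4 (684). For Suz12Plt8/+ the highest set apart wild-type replicates 2, 3 and 4 with Suz12Plt8/+ replicate 4 (754). These groups follow mouse line in part: replicates 2 and 4 are the Bmi1+/+ arrays, and 5 and 6 are Yy1+/+ arrays. The Suz12+/+ arrays, replicates 1 and 3, fell in different groups. Between mutants, 1 of 35 splits, the real one, reached 3 genes (Bmi1-/- against Suz12Plt8/+), 36 (Bmi1-/- against Yy1+/-) and 76 (Suz12Plt8/+ against Yy1+/-), with 0 in the highest other split. Each mutant comes from its own mouse line, so these splits cannot separate genotype from line, and the counts were lower against line-matched wild types. For lists the share was below 5% in Bmi1-/- against wild type alone (4 of 100, real 11, highest other 13), again without adjustment over the comparisons. Chance was not excluded for lists in Suz12Plt8/+ (5 of 100, real 9, highest other 12), Yy1+/- (7 of 100, real 11, highest other 17), Bmi1-/- against Suz12Plt8/+ (13 of 35, real 6, highest other 10), Bmi1-/- against Yy1+/- (3 of 35, real 13, highest other 14) or Suz12Plt8/+ against Yy1+/- (16 of 35, real 5, highest other 8).

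Hepatocyte genes were higher in Suz12Plt8/+ and Yy1+/- than in wild type, and RNA of hepatocytes among the sorted cells may be the cause, although the sort for c-Kit and Sca-1 is meant to leave hepatocytes out. Inside groups the genes of the list rose and fell together, with a mean pairwise correlation of 0.6663, where the highest of 1000 random lists reached 0.195. A difference between the genotypes fits as well, since the larger of the exact permutation p-values was 0.03636, although both were 0.0545 after adjustment over the mutants. The tests do not separate more hepatocyte RNA in mutant samples from a change inside LSK cells.

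Eosinophil granule genes were higher in Bmi1-/-, and eosinophils or their precursors among the sorted cells could account for this, although the lineage-negative gate is meant to remove mature eosinophils. The mean of 8 other eosinophil genes differed too, at an exact permutation p of 0.008333, the smallest that 120 permutations allow, with Prg3 at 1.43 (SE 0.31) and Cebpe at 0.95 (SE 0.26), but 4 of the 8 were not higher and none passed singly. Probes that read near-identical Ear genes are not the whole cause, because the 2 unrelated genes Prg2 and Epx passed with every Bmi1-/- array above every wild-type array. A difference between the Bmi1 line and the other lines did not show in the size of the change. The median change was 1.74 against Bmi1+/+ arrays and 1.73 against all wild types. It was not excluded, because there are only 2 Bmi1+/+ arrays and they are also among the wild types used for the calls. An effect of Bmi1 on these genes within progenitors was not tested apart from a change in cell types.

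For the genes called in Yy1+/- against wild type, donor-strain DNA on the chromosome of the targeted allele was weighed and excluded as the main cause. Of the 32 called genes with a known location 1 lay on chromosome 12, where 1.07 were expected. This count does not cover donor DNA on other chromosomes. Within 20 Mb of the Suz12 probe on chromosome 11 lay 5 of the called genes. There 11.9% of 430 genes had an unadjusted p below 0.05, against 9.57% of the others (Fisher's exact p = 0.114). A difference between the Yy1 line and the other lines did not show in the genes called in Yy1+/-. The median ratio of changes against wild types of the same line to those against all was 0.9984, and all 33 genes kept their direction. The Yy1+/+ arrays are also among the wild types used for the calls, so this is not an independent test. For release of germ-line genes, 14 other germ-line genes gave a camera p of 0.8149. Their median log2 change was 0.04, with 9 higher, from -0.87 (Spo11) to 0.215 (Syce2), and none passed. A general rise of the size seen for Hormad2 (1.33) was thus not seen in these 14 genes. Whether release was limited to some germ-line genes could not be told. Within 20 Mb of the Yy1 probe 20.8% of 106 genes had an unadjusted p below 0.05, against 9.55% of the others (Fisher's exact p = 0.000673, 0.00606 after adjustment over 9 windows), with 0 called and a p of 0.178 against the wild types of the same line. In Suz12Plt8/+, which has no targeted Yy1 allele, the same window held 14.2% against 7.84% (Fisher's exact p = 0.0272, 0.0816 after adjustment), and the cause of the excess is left open.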

How the results depend on the processing

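Of the results for single genes, leaving out 1 array left 508 the same, 110 weaker, 3 stronger and 0 reversed, and the other settings 807, 99, 32 and 1. For lists these were 456 the same and 47 weaker, then 678 the same, 87 weaker and 5 reversed. List calls lost most often were macrophage genes in Yy1+/- against wild type (12 of 25 alternatives) and, in Bmi1-/- against Suz12Plt8/+, Polycomb-bound regulators (12 of 21, and 1 reversed), megakaryocyte genes (11 of 21) and hepatocyte genes (9 of 21). Others were mast cell genes in Bmi1-/- against Yy1+/- (10 of 21), megakaryocyte genes in Bmi1-/- against wild type (9 of 24), heat shock genes in Yy1+/- against wild type (8 of 25), and T cell genes in Bmi1-/- against Yy1+/- and proliferation genes in Yy1+/- against wild type (5 each). Where a count fell because fewer arrays were used, the alternative's construction is enough to cause it; otherwise the cause was not tested. Signal over background limits what could be seen, since 35.8% to 39.9% of probes were detected per array.

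In a fit of only the groups compared, the genes called were 4 for Bmi1-/- against wild type, 3 for Suz12Plt8/+ against wild type, 20 for Yy1+/- against wild type, 156 for Bmi1-/- against Suz12Plt8/+, 20 for Bmi1-/- against Yy1+/- and 142 for Suz12Plt8/+ against Yy1+/-. With line-matched wild types they were 3, 0, 1 (Bmi1-/- against Suz12Plt8/+), 2 (Bmi1-/- against Yy1+/-) and 6 (Suz12Plt8/+ against Yy1+/-). The lists called were 2 (Bmi1-/- against Yy1+/-) and 1 (Suz12Plt8/+ against Yy1+/-). Results that reversed with them were the Bmi1 gene in Bmi1-/- against wild type (0.5232), the list Interferon-stimulated genes in Bmi1-/- against Yy1+/- (median log2 -0.06602), the list Megakaryocyte and platelet genes in Bmi1-/- against Yy1+/- (-0.1412) and the correlation of Suz12Plt8/+ with Yy1+/- (-0.1061). The correlation of Bmi1-/- with Yy1+/- kept its sign (0.02551). The median of the list Interferon-stimulated genes in Bmi1-/- against Suz12Plt8/+ shrank from 0.2402 to 0.02317 without changing sign, and only the direction of camera's test turned (adjusted p = 0.9048). Replicate numbers were checked for pairing from the deviations of arrays from their group means. In all, 9 of 21 pairs with the same number correlated above 0.1 (-0.245 to 0.378; median 0.0737, against -0.00122 for other pairs), and 4 of 15 arrays correlated best with an array of their own number. All 6 pairs among the arrays numbered 1 were above 0.1 (0.153 to 0.337), so these share structure, but the numbers as a whole did not pair samples. With the replicate number as a block, the genes called were 2 for Bmi1-/- against wild type, 2 for Suz12Plt8/+ against wild type, 17 for Yy1+/- against wild type and 20 for Bmi1-/- against Yy1+/-. A block for slides was not run.

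With array weights the genes called were 6 for Suz12Plt8/+ against wild type, 73 for Yy1+/- against wild type, 32 for Bmi1-/- against Suz12Plt8/+, 139 for Bmi1-/- against Yy1+/-, 385 for Suz12Plt8/+ against Yy1+/- and 93 for Wild-type lines (Suz12+/+, Bmi1+/+ and Yy1+/+ wild types), and 3 lists for Bmi1-/- against Suz12Plt8/+. With the mean of all probes of a gene they were 9 for Suz12Plt8/+ against wild type, 50 for Yy1+/- against wild type and 8 for Bmi1-/- against Suz12Plt8/+. With no detection filter they were 2 for Suz12Plt8/+ against wild type, 7 for Bmi1-/- against Suz12Plt8/+ and 4 for the wild-type lines, and the list Developmental regulators commonly bound by Polycomb reversed in Bmi1-/- against Suz12Plt8/+ (-0.02555). With a detection p below 0.01 they were 1 for Bmi1-/- against Suz12Plt8/+ and 1 for the wild-type lines. With no mean-variance trend they were 5 for Suz12Plt8/+ against wild type and 1 for the wild-type lines. Median scaling, under which the median log2 change of all genes was 0.18 in Bmi1-/- against Suz12Plt8/+ and 0.15 in Bmi1-/- against Yy1+/- (0.04 and 0.02 otherwise), gave 15 for Bmi1-/- against Suz12Plt8/+, 15 for Suz12Plt8/+ against Yy1+/- (11 up and 4 down, against 65 and 11) and 85 for Wild-type lines (Suz12+/+, Bmi1+/+ and Yy1+/+ wild types). Quantile normalization and the authors' values gave 1 each for the wild-type lines, and in Yy1+/- against wild type 10 up and 18 down, against 7 and 26. Their rises, falls and median changes were the same in all 6 comparisons. They are therefore not separate alternatives, although the tallies of alternatives count both.

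Camera with an estimated correlation called 3 lists for Bmi1-/- against wild type, 0 for Suz12Plt8/+ against wild type, 0 for Yy1+/- against wild type, 0 for Bmi1-/- against Suz12Plt8/+, 3 for Bmi1-/- against Yy1+/- and 0 for Suz12Plt8/+ against Yy1+/-, and fry 6, 0, 0, 2, 8 and 2. Of the alternatives chosen after seeing the data, leaving out wild-type arrays 2 and 3 gave 21, 3, 60, 14, 94 and 172 genes in the same order, and 3 lists for Bmi1-/- against Suz12Plt8/+. The hepatocyte list mean as a covariate gave 3 lists for Bmi1-/- against Suz12Plt8/+, and by construction the list Hepatocyte genes in Bmi1-/- against wild type reversed (-0.005336).

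Leaving out each array in turn, the genes called ranged from 2 to 11 for Bmi1-/- against wild type, 1 to 2 for Suz12Plt8/+ against wild type, 16 to 47 for Yy1+/- against wild type, 2 to 6 for Bmi1-/- against Suz12Plt8/+, 11 to 44 for Bmi1-/- against Yy1+/-, 26 to 72 for Suz12Plt8/+ against Yy1+/- and 0 to 683 for Wild-type lines (Suz12+/+, Bmi1+/+ and Yy1+/+ wild types). The lists called ranged from 10 to 14, 9 to 12, 8 to 14, 2 to 8, 12 to 15 and 5 to 10 in the same order of comparisons. The correlations ranged from 0.124 to 0.352 (Bmi1-/- with Suz12Plt8/+), 0.0995 to 0.410 (Bmi1-/- with Yy1+/-) and 0.183 to 0.394 (Suz12Plt8/+ with Yy1+/-).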

Other observations

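Xist, the RNA of the inactive X chromosome, was at background on wild-type replicate 6 alone (4.72). The Y-linked gene Eif2s3y was detected on every array, from 7.758 on wild-type replicate 4 to 9.996 on wild-type replicate 6. The arrays with Xist therefore held RNA of both sexes, and the labels do not say whether embryos were pooled.

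The first principal component set wild-type replicates 1, 5, 6 and 7 (33.4, 29.0, 26.2 and 12.7) apart from replicates 4, 3 and 2 (-15.7, -34.7 and -50.4). The Yy1+/+ arrays are replicates 5, 6 and 7 and the Bmi1+/+ arrays 2 and 4, so only the Suz12+/+ pair was split. Arl5a read 7.55 in wild types of the Bmi1 line, 9.26 in those of the Suz12 line and 9.47 in those of the Yy1 line (adjusted p = 0.0583 in limma's F test, not passing).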
